A study of Homo sapiens with 9 samples.

How the data were processed

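RNA was sequenced in 9 samples of MCF10A, an established and non-tumorigenic human breast epithelial cell line. The labels put 3 samples in each of 3 groups: an untreated control, a high calcium group given 10 mM calcium together with the calcium ionophore ionomycin (labelled as 1 mM, a dose given here as labelled), and a TGFb3 group given 10 nM transforming growth factor beta 3. Both treatments lasted 16 h. The labels number the replicates of each group but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

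Per the labels' protocols, RNA was extracted with Trizol and read as paired ends of 101 bp on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 as a tool and hg38 as the genome build. The version of HISAT2, the program that turned alignments into expression values, the annotation release, the strandedness of the libraries and the selection of poly(A) RNA are not given in the sources used here. The authors deposited 1 table of TPM values (transcripts per 1000000, a length-normalised share of each library scaled to 1000000) for 58288 annotated genes in the 9 samples. Each sample column was matched to its sample by the label, and 0 columns were left unmapped. TPM keeps no sequencing depth, so the depth of each sample is unknown and no interval for counting error is given. TPM is a share of a fixed total, so a change in very abundant RNAs moves the values of all others. Reads from overlapping genes, antisense partners and near-identical gene copies could have been split between entries in ways that cannot be checked here.

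The table pairs each Ensembl identifier with a gene symbol. The 1932 entries that share 253 symbols were summed on the linear scale, among them 45 entries for the copies of pseudoautosomal genes, which left 56609 symbols. Of these, 56352 were matched to GENCODE release 29, a hg38 annotation, from which the coordinates, gene types and overlaps given here were taken. Coordinates are 1-based.

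Values were tested as log2(TPM + 1) over the 13968 symbols with a mean of at least 1 TPM over all 9 samples. A fold change on this scale understates the change of genes with low values. A linear model with all 9 samples and the 3 groups was fitted with limma 3.58.1 in R 4.3.3, with an empirical Bayes variance that follows a trend with expression and 6 residual degrees of freedom. The comparisons were high calcium against control, TGFb3 against control, and high calcium against TGFb3. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within a comparison. A single value per sample was compared by an exact permutation test, whose smallest two-sided p with 3 samples against 3 is 0.1. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

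Before the data were examined, 36 gene lists were fixed from general knowledge, covering lysosomal, calcium, stress, TGF-beta, epithelial, inflammatory, cell cycle and metabolic genes, RNA quality and markers of other cell types. A list with at least 5 tested members was tested against all other genes with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the 33 such lists within a comparison, and again with a correlation estimated per list. For each list the members called over all genes are given, and also those called with p adjusted over the list alone. Genes named in the text follow a rule fixed at the same time: the 8 largest called rises and falls against the control, and the 5 between the treatments, with a mean of at least 10 TPM in the higher group, no overlap of the samples and a gene name rather than a clone name; up to 4 called members of each list; and a set of genes named whatever their values. Not every gene the rule picks is named. Nuclear-encoded genes with the largest falls in high calcium were added after the values were seen, because mitochondrial genes filled that part of the rule.

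Both treatments share the same control samples. The correlation, covariance and overlap of their log2 differences were therefore set beside 100 simulated pairs of unchanged groups that shared simulated controls. The overlap was also set beside that of independent lists of the same sizes. The methods were tested on simulated data made from the real means and spread, with 200 of 13968 genes changed. Of genes changed 1.25-, 1.5-, 2- and 4-fold, 15.5%, 65.5%, 76.5% and 91.5% were called in the right direction for high calcium. For TGFb3 these shares were 10.5%, 59.5%, 75.5% and 93%. Of the genes called in these simulations 8.8%, 3.7%, 1.3% and 6.2% were unchanged for high calcium, and 4.5%, 4.8%, 1.9% and 5.6% for TGFb3. Of 200 simulated lists without a change, 1% had a camera p under 0.05 with the preset correlation and 0% with the estimated one. Simulated genes were drawn independently, so the preset correlation is not tested for lists whose genes move together.

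The alternatives were a pseudocount of 0.1 TPM, no filter on low values, a minimum mean of 5 TPM, rescaling by median ratios, quantile normalisation, rescaling after leaving out mitochondrially encoded genes, no variance trend, only the groups compared in the fit, the replicate number as a block, and leaving out each sample in turn. One more alternative, leaving out mitochondrially encoded genes and then rescaling by median ratios, was chosen after seeing the data. Median ratio rescaling divides each sample by the median of its ratios to the geometric mean of each gene, over genes with a mean of at least 10 TPM. Ranges of an adjusted p run from the lowest to the highest over these alternatives.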

Results

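RNA of MCF10A breast epithelial cells was measured in 3 control, 3 high calcium and 3 TGFb3 samples, the treated ones after 16 h. The table gives TPM, whose total is 1000000 in every sample, so the sequencing depth behind each value is unknown. TPM is given as mean ± SD over the 3 samples of a group, and a log2 difference of log2(TPM + 1) with its standard error from the limma fit (n = 3 in each group). Adjusted p-values of genes come from limma and those of gene lists from camera. Symbols with at least 1 TPM numbered 13394 ± 114 in the controls, 14469 ± 38 in high calcium and 13578 ± 28.7 in TGFb3. Across genes, which are not independent replicates, the correlation of log2 values was 0.987 to 0.991 between samples of the same group and 0.926 to 0.944 between groups. The first principal component held 50% of the variance and set the high calcium samples apart, and the second held 35.2% and set the controls apart.

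RNA encoded by the mitochondrial genome took 22.7 ± 0.91% of TPM in the controls. Its share was 11.5 ± 0.37% in high calcium (exact permutation p = 0.1, the smallest that 3 samples against 3 can give) and 22.7 ± 0.59% in TGFb3 (exact permutation p = 0.9). MALAT1, a nuclear noncoding RNA often read as a sign of RNA quality, was at 158 ± 45 TPM in the controls. It was at 424 ± 32 TPM in high calcium (exact permutation p = 0.1) and 204 ± 12 TPM in TGFb3 (exact permutation p = 0.3).

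High calcium against control addressed how these cells respond to a raised calcium level, which the series title ties to milk stasis and lysosomal cell death. Calcium and ionomycin were given together and no group had either alone, so their effects cannot be told apart. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 298 ± 7.61 to 2962 ± 11.4 TPM, a 9.9-fold change of TPM + 1, and all 29 measured genes of the unfolded protein response rose. RCAN1, a target and regulator of the calcium-dependent phosphatase calcineurin, rose from 16 ± 0.7 to 170 ± 1.26 TPM. SPRR1A, a cornified envelope protein, rose from 6.24 ± 0.874 to 206.5 ± 19.4 TPM, and LCN2, a secreted iron-binding protein of inflamed epithelium, from 9.06 ± 0.353 to 133 ± 6.73 TPM. All 48 S phase genes and all 47 mitosis genes fell, MKI67 from 166.5 ± 5.08 to 50.1 ± 1.91 TPM. All 13 mitochondrial messenger RNAs fell while both mitochondrial ribosomal RNAs rose.

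The test called 6438 genes higher and 2378 lower of 13968, of which 1465 and 357 changed by a log2 of 1 or more (845 and 649 after quantile normalisation). The samples of the groups did not overlap in 69% of genes, where chance gives 10%. Of the calls 73% were higher. That share was 56% (4714 higher, 3703 lower) after median ratio rescaling, 55.1% (4649 and 3791) with mitochondrial genes left out and 47.2% (3991 and 4464) after quantile normalisation. With both of the first steps, an alternative chosen after seeing the data, it was 55.9%. The median log2 difference of all tested genes was 0.22. Relative to that median the differences were 4.62 for SPRR1A, 3.08 for HSPA5, 2.98 for DDIT3, 2.52 for WIPI1, 0.50 for CTSD and -1.94 for MKI67. In both comparisons with high calcium, counts of list members after median ratio rescaling stand beside those from TPM as deposited. Where an adjusted p under an alternative is given, the range is that over all 17 to 19 alternatives for the result.

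Genes of endoplasmic reticulum stress rose with few exceptions. The unfolded protein response rose in 29 of 29 cases, with the same counts adjusted over the list alone and 29 higher and 0 lower after median ratio rescaling, and had a camera adjusted p of 4.7e-15 (adjusted p = 0.063 with an estimated correlation, range 9e-23 to 0.063). HSPA5 (chromosome 9, 125234853 to 125241330) rose by log2 3.31 ± 0.038 (adjusted p = 1.5e-11), CRELD2 by 2.93 ± 0.067 and HERPUD1, which acts in the degradation of misfolded proteins, by 2.92 ± 0.077. Among targets of ATF4, the transcription factor of the integrated stress response, 26 of 27 rose and 1 was not called, with the same counts adjusted over the list alone and 24 higher and 1 lower after median ratio rescaling. The ATF4 targets had a camera adjusted p of 4.6e-08 (adjusted p = 0.085 with an estimated correlation, range 2.9e-13 to 0.085). DDIT3, a transcription factor linked to cell death under stress, rose from 19.2 ± 2.14 to 184 ± 7.64 TPM (chromosome 12, 57516588 to 57521737, where it overlaps MBD6 and MARS). GDF15, a stress-induced secreted factor, rose by log2 3.53 ± 0.073 and PPP1R15A by 2.63 ± 0.069. The cytosolic heat shock list went the other way, with 13 of 18 members lower, 4 higher and 1 not called, and with the same counts adjusted over the list alone and 3 higher and 13 lower after median ratio rescaling. Heat shock genes had a camera adjusted p of 3.1e-05 (adjusted p = 0.069 with an estimated correlation, range 2.3e-05 to 0.069). The chaperones CHORDC1 and DNAJA1 fell by log2 1.20 and 1.17, and the small heat shock protein CRYAB rose by 3.04 ± 0.16.

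Of 52 measured lysosomal hydrolases and activators, 40 rose, 4 fell and 8 were not called, with 42 higher and 4 lower adjusted over the list alone and 33 higher and 6 lower after median ratio rescaling. The hydrolases had a camera adjusted p of 0.00073 (adjusted p = 0.06 with an estimated correlation, range 8.6e-07 to 0.06). CTSO, a cysteine protease, rose by log2 1.79 ± 0.096, SMPD1, the acid sphingomyelinase, by 1.75 ± 0.089, and NEU1, a sialidase, by 1.31 ± 0.097. FUCA1, a fucosidase with low values, was at 0.502, 1.04 and 0.92 TPM in the controls and at 6.35, 7.14 and 5.37 TPM in high calcium. Cathepsin D (CTSD, chromosome 11, 1752752 to 1764573) rose from 99.65 ± 14.7 to 164.5 ± 7.92 TPM (log2 0.73 ± 0.12, adjusted p = 0.00034), and cathepsin L (CTSL) from 127 ± 3.47 to 192 ± 9.28 TPM. Cathepsin B (CTSB, which overlaps AC025857.2) was at 132 ± 10.3 TPM in the controls and 126 ± 12.2 TPM in high calcium (log2 -0.07 ± 0.073, adjusted p = 0.44). CTSB was called lower under the 3 other scalings, with log2 differences of -0.25 (median ratio), -0.22 (quantile) and -0.26 (mitochondrial genes left out). Mitochondrial RNA took 22.7% of TPM in the controls and 11.5% in high calcium beside these genes.

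Among 27 lysosomal membrane proteins 19 rose, 1 fell and 7 were not called, with the same counts adjusted over the list alone and 12 higher and 2 lower after median ratio rescaling. These membrane proteins had a camera adjusted p of 0.027 (adjusted p = 0.32 with an estimated correlation, range 0.00038 to 0.32). SLC17A5, a sialic acid exporter, rose by log2 1.24 ± 0.073, the cholesterol exporter NPC1 by 0.81 ± 0.042 and LAMP2 from 113 ± 3.96 to 177.5 ± 3.24 TPM. LAMP1 went from 84.8 ± 2.19 to 102 ± 2.11 TPM (log2 0.26 ± 0.043, adjusted p = 4e-04) but was not called under the 3 other scalings, where its log2 difference was 0.09, 0.09 and 0.07. Of 21 vacuolar ATPase subunits, which acidify lysosomes, 14 rose, 1 fell and 6 were not called, with the same counts adjusted over the list alone and 10 higher and 2 lower after median ratio rescaling. The subunits had a camera adjusted p of 0.066, and were called with quantile normalisation (adjusted p = 0.041) and with no filter on low values (adjusted p = 0.0048, range 0.0048 to 0.35). ATP6V1C2 rose by log2 2.91 ± 0.13 and ATP6V0A4 by 1.44 ± 0.11.

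Autophagy genes rose in 29 of 40 cases, fell in 4 and were not called in 7, with 30 higher and 4 lower adjusted over the list alone and 22 higher and 7 lower after median ratio rescaling. Autophagy genes had a camera adjusted p of 0.0093 (adjusted p = 0.069 with an estimated correlation, range 7.7e-05 to 0.069). WIPI1, which acts in autophagosome formation, rose from 11.1 ± 0.318 to 79.6 ± 2.45 TPM (chromosome 17, 68420948 to 68457513, overlapping ARSG), and the receptor SQSTM1, which overlaps MGAT4B and MRNIP, from 144 ± 3.86 to 377 ± 25 TPM. In the list of MiT/TFE factors, regulators of lysosomal genes, and their feedback genes, 8 of 10 rose, 1 fell and 1 was not called, with the same counts adjusted over the list alone and 8 higher and 1 lower after median ratio rescaling. The MiT/TFE list had a camera adjusted p of 0.088. It was called after median ratio rescaling (adjusted p = 0.042), with mitochondrial genes left out (0.043) and with no filter (0.0087, range 0.0087 to 0.24). TFEB rose from 3.13 ± 0.0752 to 5.675 ± 0.415 TPM (log2 0.69 ± 0.095) and TFE3 by log2 0.56 ± 0.062. GPNMB was at 0.356, 0.432 and 0.061 TPM in the controls and at 5.25, 3.65 and 4.65 TPM in high calcium.

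Of 10 genes of calcineurin and NFAT 6 rose and 4 were not called, with the same counts adjusted over the list alone and 3 higher and 1 lower after median ratio rescaling and a camera adjusted p of 0.31. RCAN1 (chromosome 21, 34513142 to 34615142) rose by log2 3.33 ± 0.049 (adjusted p = 6.6e-11), RCAN2 by 0.95 ± 0.15 and NFAT5 by 0.52 ± 0.099. Calcium transport, sensing and buffering genes rose in 16 of 25 cases, fell in 2 and were not called in 7, with the same counts adjusted over the list alone and 15 higher and 4 lower after median ratio rescaling. The calcium list had a camera adjusted p of 0.069, and was called with quantile normalisation (adjusted p = 0.041) and with no filter (0.0034, range 0.0034 to 0.24). The store-operated calcium channel ORAI3 rose by log2 2.64 ± 0.29, its sensor STIM1 by 1.29 ± 0.062 and the plasma membrane calcium pump ATP2B1 by 0.97 ± 0.057. ATP2B2, the pump of lactating mammary cells, was listed at 0 in all 9 samples. Immediate early genes rose in 13 of 17 cases, fell in 3 and were not called in 1, with the same counts adjusted over the list alone and 13 higher and 4 lower after median ratio rescaling. Early genes had a camera adjusted p of 0.042 (adjusted p = 0.39 with an estimated correlation, range 0.0037 to 0.39), and their call was lost without TGFb3 2 (adjusted p = 0.053) or TGFb3 3 (0.051), with a minimum of 5 TPM (0.09) and with only the compared groups in the fit (0.065). ATF3 rose by log2 2.82 ± 0.16 and JUN by 2.34 ± 0.053, and EGR1 fell by 2.52. Of 13 S100 proteins, which bind calcium, 6 rose and 7 fell, with the same counts adjusted over the list alone and 5 higher and 7 lower after median ratio rescaling and a camera adjusted p of 0.29. S100A4 rose by log2 1.53 ± 0.15 and S100A14 fell by 0.82.

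Inflammatory targets of NF-kappaB rose in 24 of 27 cases and were not called in 3, with the same counts adjusted over the list alone and 23 higher and 0 lower after median ratio rescaling. NF-kappaB targets had a camera adjusted p of 1.3e-06 (adjusted p = 0.16 with an estimated correlation, range 7.8e-10 to 0.16). The chemokine CXCL8 rose from 38.5 ± 3 to 436 ± 10.7 TPM, CCL20 by log2 3.35 ± 0.087 and the mitochondrial superoxide dismutase SOD2 by 2.97 ± 0.17. The cytokine IL24 (chromosome 1, 206897443 to 206904139) was at 0.33, 0 and 0 TPM in the controls and at 31.4, 31.5 and 28.8 TPM in high calcium. In the list of the STAT3 pathway and involution 21 of 25 rose, 2 fell and 2 were not called, with the same counts adjusted over the list alone and 18 higher and 2 lower after median ratio rescaling. The STAT3 list had a camera adjusted p of 0.003 (adjusted p = 0.08 with an estimated correlation, range 2.3e-05 to 0.08). CLU rose by log2 2.16 ± 0.11, STAT3 from 95.5 ± 0.815 to 149 ± 8.68 TPM and its feedback inhibitor SOCS3 by log2 0.96 ± 0.11. LIF, a cytokine that activates STAT3, had a log2 difference of 0.53 ± 0.16 (adjusted p = 0.016, range 0.0032 to 0.4). Its call was lost without control 1 (adjusted p = 0.057), high calcium 1 (0.051) or high calcium 3 (0.05) and under the 3 other scalings (0.07, 0.4 and 0.082). Interferon-stimulated genes rose in 20 of 28 cases, fell in 1 and were not called in 7, with the same counts adjusted over the list alone and 16 higher and 3 lower after median ratio rescaling. Interferon genes had a camera adjusted p of 0.061, and were called without control 3 (0.043) or high calcium 1 (0.036), under the 3 other scalings (0.038, 0.041 and 0.039) and with no filter (0.0034, range 0.0034 to 0.37). IFIT2 rose by log2 1.84 ± 0.083.

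Keratinocyte differentiation genes rose in 19 of 23 cases, fell in 2 and were not called in 2, with the same counts adjusted over the list alone and 18 higher and 2 lower after median ratio rescaling. Keratinocyte genes had a camera adjusted p of 0.0045 (adjusted p = 0.37 with an estimated correlation, range 1e-04 to 0.37), and the call was lost with no filter on low values (adjusted p = 0.076). SPRR1A (chromosome 1, 152985231 to 152985500) rose by log2 4.84 ± 0.20 and SPRR2D by 4.50 ± 0.12, both from a family of similar genes, and KRT80 by 2.85 ± 0.13. The protease inhibitor SERPINB13 went from 7.52 ± 1.58 to 150 ± 1.54 TPM. In the luminal and milk list 12 of 16 rose and 4 were not called, with the same counts adjusted over the list alone and 10 higher and 1 lower after median ratio rescaling. Luminal and milk genes had a camera adjusted p of 0.0066 (adjusted p = 0.24 with an estimated correlation, range 0.00038 to 0.24). LCN2 (chromosome 9, 128149071 to 128153455) rose by log2 3.73 ± 0.084, XDH, an enzyme of milk fat secretion, by 2.20 ± 0.094 and the mucin MUC1 by 1.64 ± 0.21. Epithelial junction genes rose in 14 of 27 cases, fell in 5 and were not called in 8, with the same counts adjusted over the list alone and 14 higher and 5 lower after median ratio rescaling and a camera adjusted p of 0.23. The splicing factor ESRP1 rose by log2 3.73 ± 0.19 and CDH1, the E-cadherin gene, which overlaps FTLP14, from 94.3 ± 7.03 to 153 ± 2.83 TPM. Of 19 basal epithelial genes 13 rose, 4 fell and 2 were not called, with the same counts adjusted over the list alone and 10 higher and 5 lower after median ratio rescaling. Basal genes had a camera adjusted p of 0.2, called with quantile normalisation (0.05, range 0.05 to 0.37), and the laminin LAMB3 rose by log2 2.12 ± 0.068.

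TGF-beta and SMAD targets were higher in 17 of 29 cases, lower in 6 and not called in 6, with the same counts adjusted over the list alone and 15 higher and 9 lower of 30 after median ratio rescaling and a camera adjusted p of 0.34. IGFBP3 rose by log2 2.37 ± 0.13 and ID2 fell by 1.61. SMAD7 had a log2 difference of 0.24 ± 0.094 (adjusted p = 0.046, range 0.022 to 0.47), which was -0.15 after quantile normalisation. Its call was lost without control 1, 2 or 3 (adjusted p = 0.11, 0.05 and 0.091), high calcium 2 or 3 (0.13 and 0.14) or TGFb3 1, 2 or 3 (0.062, 0.062 and 0.053). That call was also lost under the 3 other scalings (0.41, 0.21 and 0.47), with no filter (0.067) and with only the compared groups (0.09). Ligands, receptors and SMADs rose in 10 of 17 cases, fell in 2 and were not called in 5, with the same counts adjusted over the list alone and 8 higher and 4 lower after median ratio rescaling and a camera adjusted p of 0.31. The receptor TGFBR2 fell by log2 0.27. The TGFB3 gene, which overlaps IFT43, had a log2 difference of 0.52 ± 0.25 (adjusted p = 0.092), called without high calcium 1 (0.83, adjusted p = 0.0035, range 0.0035 to 0.69). Among mesenchymal and matrix genes 17 of 34 rose, 7 fell and 10 were not called, with 17 higher and 8 lower adjusted over the list alone and 15 higher and 10 lower after median ratio rescaling and a camera adjusted p of 0.75. The matrix glycoprotein TNC rose by log2 4.13 ± 0.14 and the actin-binding TAGLN fell by 1.81. FN1, the fibronectin gene, had a log2 difference of 0.01 ± 0.063 (adjusted p = 0.92), and was called lower under the 3 other scalings (-0.17, -0.17 and -0.19, adjusted p = 0.034, 0.031 and 0.034, range 0.031 to 0.98).

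S phase and replication genes fell in 48 of 48 cases, with the same counts adjusted over the list alone and 0 higher and 48 lower after median ratio rescaling, and had a camera adjusted p of 6e-37 (adjusted p = 0.0064 with an estimated correlation, range 8.1e-50 to 0.0064). The helicase component GINS2, which overlaps GSE1, fell by log2 2.35, the nuclease EXO1 by 2.04 and the chromatin remodeller HELLS by 2.02. Genes of G2/M and mitosis fell in 47 of 47 cases, with the same counts adjusted over the list alone and 0 higher and 47 lower after median ratio rescaling, and had a camera adjusted p of 1.2e-37 (adjusted p = 0.06 with an estimated correlation, range 2.1e-50 to 0.06). The transcription factor MYBL2 fell by log2 1.76 and MKI67 by 1.71. FAM111B, named after its value was seen, fell from 33.55 ± 0.727 to 4.82 ± 0.0755 TPM. Targets of p53 rose in 18 of 28 cases, fell in 4 and were not called in 6, with the same counts adjusted over the list alone and 16 higher and 6 lower after median ratio rescaling. The p53 targets had a camera adjusted p of 0.069, and were called without control 3 (0.043), under the 3 other scalings (0.038, 0.017 and 0.038) and with no filter (0.0048, range 0.0048 to 0.33). BBC3, a cell death gene, rose by log2 1.66 ± 0.11. Of 35 apoptosis regulators 15 rose, 9 fell and 11 were not called, with the same counts adjusted over the list alone and 13 higher and 14 lower after median ratio rescaling and a camera adjusted p of 0.58. BIRC3 rose by log2 1.09 ± 0.062 and BIRC5 fell by 0.94. The apoptosis list had a median log2 difference of 0.16, which turned to -0.02 after median ratio rescaling, and the S100 list a mean of 0.01 and a median of -0.33, both with a camera direction of down.

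Cholesterol synthesis genes rose in 23 of 24 cases and fell in 1, with the same counts adjusted over the list alone and 21 higher and 1 lower after median ratio rescaling. Cholesterol genes had a camera adjusted p of 3.9e-07 (adjusted p = 0.11 with an estimated correlation, range 1.1e-11 to 0.11), and HMGCS1 rose from 264.5 ± 12.2 to 1012 ± 10.1 TPM. Of NRF2 targets, genes of the response to oxidants, 18 of 24 rose, 2 fell and 4 were not called, with the same counts adjusted over the list alone and 16 higher and 3 lower after median ratio rescaling. NRF2 targets had a camera adjusted p of 0.0084 (adjusted p = 0.19 with an estimated correlation, range 0.00011 to 0.19), with AKR1C1, one of several near-identical genes, up by log2 3.00 ± 0.12 and HMOX1 by 2.94 ± 0.21. Glycolysis and hypoxia genes rose in 17 of 30 cases, fell in 7 and were not called in 6, with 18 higher and 7 lower adjusted over the list alone and 12 higher and 9 lower after median ratio rescaling and a camera adjusted p of 0.65. NDRG1 rose by log2 1.94 ± 0.057. GAPDH, which overlaps AC006064.4, had a log2 difference of 0.16 ± 0.061 (adjusted p = 0.047, range 0.032 to 0.76) that turned to -0.02 after median ratio rescaling and -0.04 without mitochondrial genes. Its call was lost without control 1 (adjusted p = 0.17), high calcium 1, 2 or 3 (0.11, 0.08 and 0.1) or TGFb3 2 or 3 (0.056 and 0.058). The GAPDH call was also lost under the 3 other scalings (0.76, 0.26 and 0.58), with no filter (0.12), with no variance trend (0.08) and with only the compared groups (0.061). Cytosolic ribosomal protein genes were higher in 29 of 67 cases, lower in 2 and not called in 36, with 25 higher and 2 lower adjusted over the list alone and 12 higher and 14 lower after median ratio rescaling and a camera adjusted p of 0.31. Of 4 metallothioneins MT1F (log2 1.57 ± 0.11), MT1X (0.62 ± 0.062) and MT1E (0.17 ± 0.052) were called higher and MT2A (-0.19 ± 0.044) lower, and MT1E turned to -0.01 after median ratio rescaling and -0.02 without mitochondrial genes. Replication-dependent histones are a class whose transcripts mostly lack a poly(A) tail, but gene-level values do not show which transcript form was counted. They rose in 5 of 6 cases and were not called in 1, with the same counts adjusted over the list alone and 5 higher and 0 lower after median ratio rescaling. Histones had a camera adjusted p of 0.076, called under the 3 other scalings (0.038, 0.042 and 0.035, range 0.035 to 0.29).

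Mitochondrial messenger RNA took 21.6 ± 0.94% of TPM in the controls and 4.94 ± 0.13% in high calcium (exact permutation p = 0.1). Mitochondrial ribosomal RNA took 0.716 ± 0.06% and 6.26 ± 0.25% (exact permutation p = 0.1). MT-ND3, a complex I subunit at 10059 to 10404 of the mitochondrial genome, fell from 7428 ± 189 to 586 ± 37.7 TPM, and MT-CO2, a complex IV subunit, from 28300 ± 1960 to 2347 ± 115 TPM. The smallest fall was that of MT-ND1 (log2 -0.50 ± 0.073). MT-RNR2, the large ribosomal RNA, rose from 5534 ± 419 to 52530 ± 2220 TPM and MT-RNR1, the small one, from 1630 ± 184 to 10040 ± 306 TPM. This list of 15 genes had 2 higher and 13 lower, also adjusted over the list alone and after median ratio rescaling. Its camera adjusted p was 4.3e-12 (0.069 with an estimated correlation, range 2.4e-13 to 0.069). Entries of mitochondrial transfer RNAs fell most among genes with at least 10 TPM in the higher group, MT-TE at log2 -4.95 ± 0.17 and MT-TC, which overlaps MT-TY, at -4.66 ± 0.36. Such reads may come from flanking transcripts, so a fall of mature transfer RNA is not shown.

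**Figure D1:**
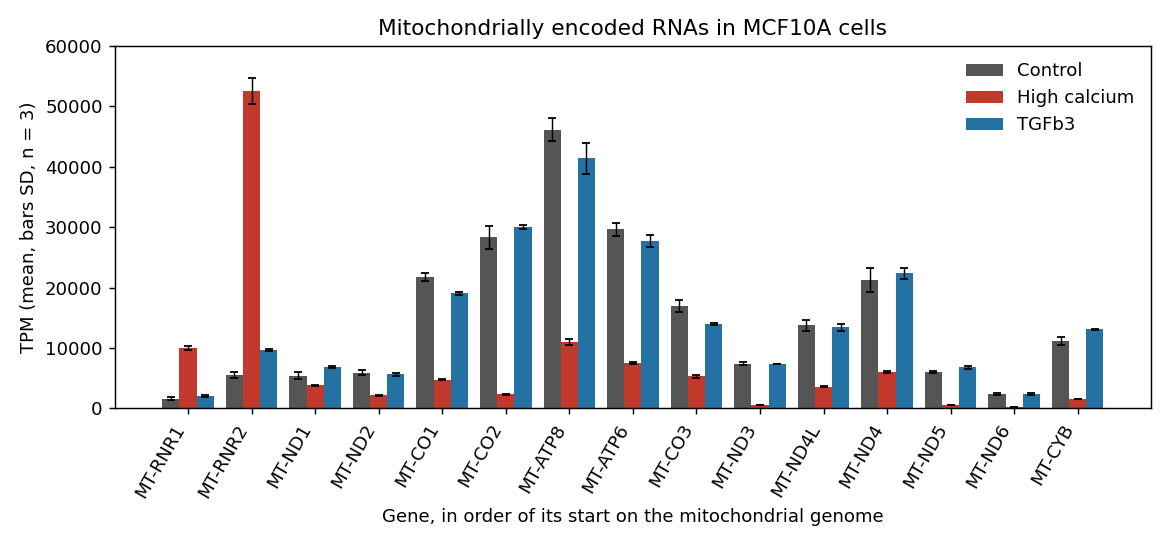
Mean TPM of the 15 mitochondrially encoded messenger and ribosomal RNAs (vertical axis, from 0) in control, high calcium and TGFb3 samples, in order of their start on the mitochondrial genome (horizontal axis), with bars for the SD of 3 samples. In high calcium MT-RNR2 stood at 52530 TPM, against 5534 TPM in the controls, and all 13 messenger RNAs were lower.

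Of 7 measured fibroblast markers 6 rose and 1 was not called, with the same counts adjusted over the list alone and 4 higher and 1 lower after median ratio rescaling and a camera adjusted p of 0.19. All 14 fibroblast markers summed to 133 TPM in the controls and 178 TPM in high calcium, and DCN rose by log2 1.43 ± 0.13. Of endothelial markers TEK (log2 1.65 ± 0.15) and KDR (0.67 ± 0.12) were called higher, KDR not after quantile normalisation (0.29, adjusted p = 0.065, range 0.00025 to 0.065). The leukocyte markers CD68 (log2 3.02 ± 0.32), CSF1R (1.58 ± 0.13) and CD14 (0.82 ± 0.13) rose, and PTPRC, the pan-leukocyte marker, was listed at 0 in all 9 samples. Camera called 12 of 33 lists up and 4 down, and the call of S phase genes alone held with an estimated correlation. Values of low genes are compressed by the pseudocount, and the smallest exact p for a single value is 0.1 with 3 samples in each group.

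**Figure D2:**
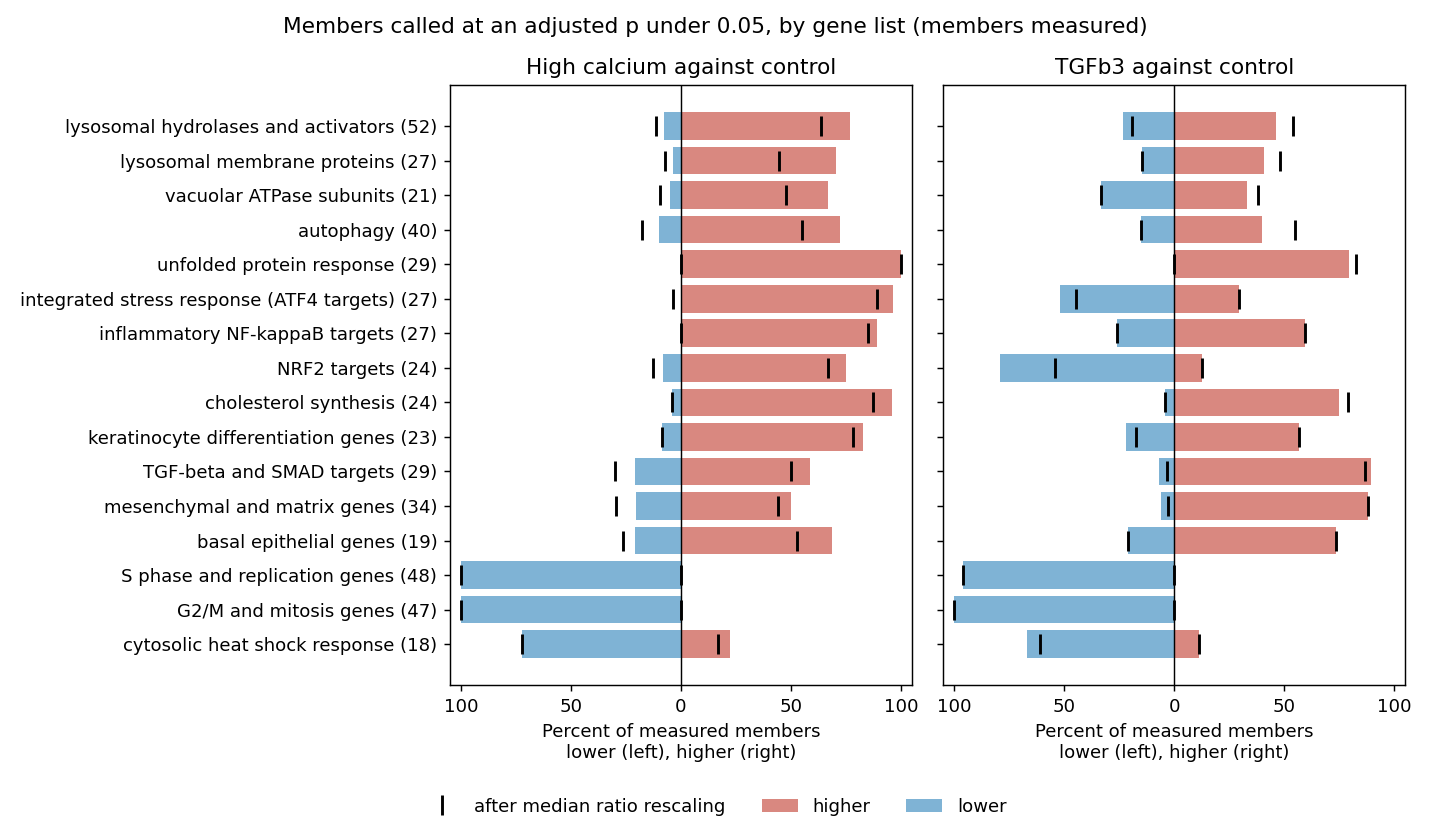
Percent of the measured members of 16 gene lists (number in brackets) called higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 in high calcium (left panel) and TGFb3 (right panel) against control, with black ticks for the percent after median ratio rescaling. All 29 unfolded protein response genes were higher in high calcium and 23 in TGFb3, and all 47 mitosis genes were lower in both.

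TGFb3 against control addressed the response to a cytokine that the series design sets beside calcium. FN1 rose from 47.7 ± 3.75 to 5276 ± 346 TPM, a 108-fold change of TPM + 1. TGF-beta targets and mesenchymal genes rose together, with 26 of 29 and 30 of 34 members higher. EHF, an epithelial transcription factor, fell from 64.1 ± 4.17 to 3.73 ± 0.705 TPM. All 47 mitosis genes and 46 of 48 S phase genes fell, and MCM2, a subunit of the replicative helicase that overlaps TPRA1, from 39.3 ± 2.23 to 13.9 ± 0.751 TPM. Cathepsin B (CTSB) rose from 132 ± 10.3 to 381.5 ± 6.95 TPM.

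**Figure D3:**
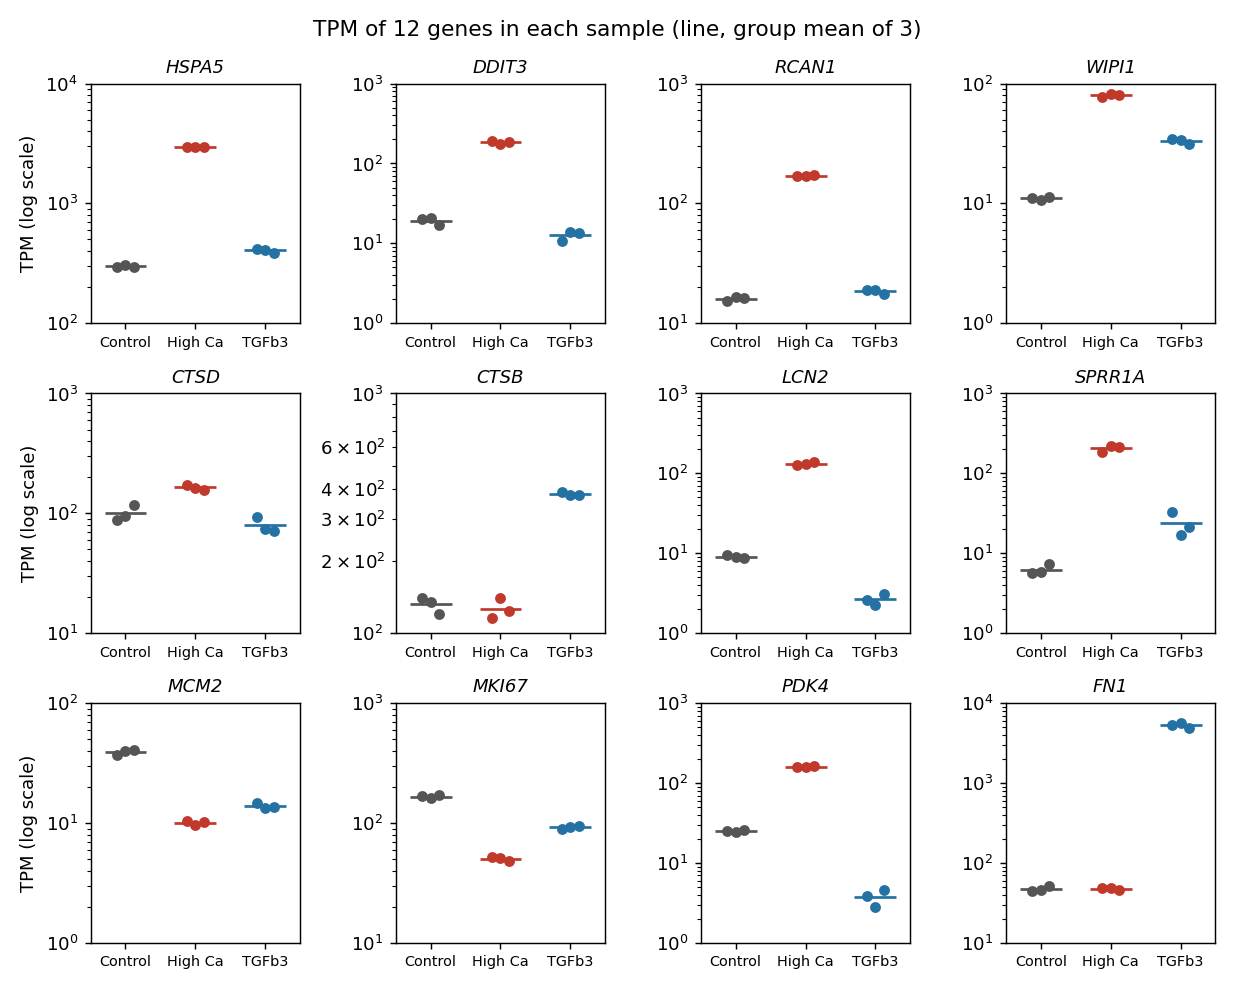
TPM (vertical axes, log scale) of 12 genes in each of the 9 samples, with points for samples and a line for the mean of the 3 samples of a group. FN1 stood at 5276 TPM in TGFb3 and HSPA5 at 2962 TPM in high calcium, while the log2 difference of FN1 between high calcium and control was 0.01 as deposited and -0.17 after median ratio rescaling, and FN1 and CTSB were called lower in high calcium only after rescaling.

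The test called 3703 genes higher and 4623 lower of 13968, of which 865 and 569 changed by a log2 of 1 or more (865 lower with a pseudocount of 0.1 TPM). The samples did not overlap in 63.8% of genes, where chance gives 10%, and the median log2 difference of all tested genes was -0.06. Of the calls 44.5% were higher, a share that turned to 51.5% (4288 higher, 4035 lower) after median ratio rescaling and was 45.4% (3795 and 4561) after quantile normalisation. FN1 (chromosome 2, 215360440 to 215436172) had a log2 difference of 6.76 ± 0.063 (adjusted p = 2e-12). KANK4 (chromosome 1, 62236979 to 62319414) was at 0.381, 0.241 and 0.325 TPM in the controls and at 64.4, 63.2 and 59.2 TPM in TGFb3. Among genes with at least 10 TPM in the higher group, further large rises were those of the potassium channel KCNJ15 (log2 5.14 ± 0.18), PLAU (4.99 ± 0.069, overlapping C10orf55), TGM2 (4.79 ± 0.061, overlapping RPRD1B) and PMEPA1 (4.48 ± 0.055, overlapping NKILA). EHF (chromosome 11, 34621093 to 34661057, log2 -3.79 ± 0.11) fell most among them, followed by the transporters SLCO4A1 (-3.01 ± 0.13) and SLC27A2 (-2.94 ± 0.099) and the aldehyde dehydrogenase ALDH3A1 (-2.81 ± 0.15). HYPK, whose reads may be shared with SERF2, fell by 2.77.

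TGF-beta and SMAD targets rose in 26 of 29 cases, fell in 2 and were not called in 1, with the same counts adjusted over the list alone and a camera adjusted p of 6.6e-16 (adjusted p = 0.0082 with an estimated correlation, range 2.8e-22 to 0.0082). The integrin ITGB6 rose by log2 3.98 ± 0.049, the matrix protein TGFBI by 3.82 ± 0.050 and the inhibitory SMAD7 by 1.85 ± 0.094. Of 34 mesenchymal and matrix genes 30 rose, 2 fell and 2 were not called, with the same counts adjusted over the list alone and a camera adjusted p of 6.7e-15 (adjusted p = 0.0082 with an estimated correlation, range 1.6e-19 to 0.0082). TNC rose by log2 4.30 ± 0.14 and the collagen COL4A1 by 3.55 ± 0.052. Ligands, receptors and SMADs rose in 9 of 17 cases, fell in 2 and were not called in 6, with the same counts adjusted over the list alone. The ligand and receptor list had a camera adjusted p of 0.0067 (adjusted p = 0.3 with an estimated correlation, range 0.00024 to 0.3). The receptor TGFBR1 rose by log2 2.45 ± 0.057 and TGFBR2 by 0.26 ± 0.035, TGFBR3 fell by 1.85, and the TGFB3 gene had a log2 difference of -0.40 ± 0.25 (adjusted p = 0.19). Of 19 basal epithelial genes 14 rose, 4 fell and 1 was not called, with the same counts adjusted over the list alone. The basal genes had a camera adjusted p of 0.00017 (adjusted p = 0.065 with an estimated correlation, range 9.5e-05 to 0.065), and the transcription factor SNAI2 rose by log2 2.38 ± 0.072. Fibroblast markers rose in 5 of 7 cases and were not called in 2, with the same counts adjusted over the list alone. Fibroblast markers had a camera adjusted p of 0.00029 (adjusted p = 0.065 with an estimated correlation, range 1e-04 to 0.065), and their 14 genes summed to 133 TPM in the controls and 585 TPM in TGFb3. FAP rose by log2 2.87 ± 0.056 and PDPN by 3.12 ± 0.081, while COL1A2, THY1 and DPT were listed at 0 in all 9 samples.

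Lysosomal hydrolases rose in 24 of 52 cases, fell in 12 and were not called in 16, with 25 higher and 12 lower adjusted over the list alone. The hydrolases had a camera adjusted p of 0.039 (adjusted p = 0.11 with an estimated correlation, range 0.025 to 0.11), a call lost without control 3 (adjusted p = 0.057) or TGFb3 1 (0.078) and with a minimum of 5 TPM (0.065). CTSV rose by log2 2.14 ± 0.16, CTSB (chromosome 8, 11842524 to 11869448) by 1.53 ± 0.073 (adjusted p = 8e-08) and SMPD1 by 1.19 ± 0.089. CTSD went from 99.65 ± 14.7 to 79.9 ± 12.1 TPM (log2 -0.32 ± 0.12, adjusted p = 0.037, range 0.006 to 0.13). It was not called without control 2 or 3 (adjusted p = 0.055 and 0.13), high calcium 2 (0.05) or TGFb3 2 or 3 (0.11 and 0.13). Median ratio rescaling (0.086), quantile normalisation (0.071), no filter (0.11), no variance trend (0.064) and only the compared groups (0.063) also lost that call. CTSL had a log2 difference of 0.21 ± 0.066 (adjusted p = 0.02, range 0.00097 to 0.078) and was not called without control 2 (0.063), TGFb3 1 (0.069) or TGFb3 2 (0.078), or with no filter (0.054). Among lysosomal membrane proteins 11 of 27 rose, 4 fell and 12 were not called, with the same counts adjusted over the list alone. These membrane proteins had a camera adjusted p of 0.0074 (adjusted p = 0.23 with an estimated correlation, range 0.00087 to 0.23). CD63 rose by log2 0.91 ± 0.037, LAMP2 by 0.71 ± 0.041 and LAMP1 by 0.16 ± 0.043 (adjusted p = 0.0083), and TPCN1, a lysosomal calcium channel, fell by 0.79.

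Vacuolar ATPase subunits rose in 7 of 21 cases, fell in 7 and were not called in 7, with the same counts adjusted over the list alone and a camera adjusted p of 0.73. ATP6V1B1 was at 7.76, 3.97 and 6.39 TPM in the controls and at 0.35, 0.179 and 0 TPM in TGFb3. Autophagy genes rose in 16 of 40 cases, fell in 6 and were not called in 18, with the same counts adjusted over the list alone. Autophagy genes had a camera adjusted p of 0.0067 (adjusted p = 0.065 with an estimated correlation, range 0.0011 to 0.065), the initiating kinase ULK1 rose by log2 1.53 ± 0.11 and WIPI1 reached 33.1 ± 1.62 TPM. Of the MiT/TFE list 5 of 10 rose and 5 were not called, with the same counts adjusted over the list alone and a camera adjusted p of 0.083. The list was called with no filter (adjusted p = 0.042, range 0.042 to 0.23), and TFEB rose by log2 0.59 ± 0.095 and TFE3 by 0.55 ± 0.062. Calcium genes rose in 14 of 25 cases, fell in 3 and were not called in 8, with 15 higher and 3 lower adjusted over the list alone. The calcium list had a camera adjusted p of 0.031 (adjusted p = 0.18 with an estimated correlation, range 0.024 to 0.18), while ATP2B1 fell by log2 0.57. Calcineurin and NFAT genes rose in 6 of 10 cases, fell in 3 and were not called in 1, with the same counts adjusted over the list alone and a camera adjusted p of 0.19, called with no filter (0.026, range 0.026 to 0.46). RCAN1 rose by log2 0.20 ± 0.049 (adjusted p = 0.0058). Immediate early genes rose in 11 of 17 cases, fell in 4 and were not called in 2, with the same counts adjusted over the list alone. Early genes had a camera adjusted p of 0.0066 (adjusted p = 0.31 with an estimated correlation, range 0.0013 to 0.31), and JUN rose by log2 2.73 ± 0.053.

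Unfolded protein response genes rose in 23 of 29 cases and were not called in 6, with the same counts adjusted over the list alone. This response had a camera adjusted p of 5.9e-08 (adjusted p = 0.11 with an estimated correlation, range 3.8e-11 to 0.11), and the coat protein SEC24D rose by log2 1.51 ± 0.056. ATF4 targets rose in 8 of 27 cases, fell in 14 and were not called in 5, with the same counts adjusted over the list alone and a camera adjusted p of 0.32, and GDF15 fell by log2 1.40. Heat shock genes fell in 12 of 18 cases, rose in 2 and were not called in 4, with the same counts adjusted over the list alone. Heat shock genes had a camera adjusted p of 0.0039 (adjusted p = 0.12 with an estimated correlation, range 8.2e-05 to 0.12), and HSPE1 fell by log2 1.53. Of 24 NRF2 targets 19 fell, 3 rose and 2 were not called, with the same counts adjusted over the list alone. NRF2 targets had a camera adjusted p of 0.00091 (adjusted p = 0.11 with an estimated correlation, range 5.8e-06 to 0.11), with GCLC, an enzyme of glutathione synthesis, down by log2 1.42 and HMOX1 up by 3.16 ± 0.21. NF-kappaB targets rose in 16 of 27 cases, fell in 7 and were not called in 4, with the same counts adjusted over the list alone. NF-kappaB targets had a camera adjusted p of 0.0074 (adjusted p = 0.38 with an estimated correlation, range 0.00077 to 0.38), and CXCL8 rose by log2 1.84 ± 0.076 and BIRC3 fell by 1.30. In the STAT3 list 12 of 25 rose, 10 fell and 3 were not called, with the same counts adjusted over the list alone and a camera adjusted p of 0.34. IL11, a cytokine of the IL6 family, was at 0.169, 0.145 and 0 TPM in the controls and at 11.8, 12.7 and 12.2 TPM in TGFb3. STAT3 fell by log2 0.40 and SOCS3 rose by 0.83 ± 0.11. LIF had a log2 difference of 0.18 ± 0.16 (adjusted p = 0.37) and was called without TGFb3 3 (0.36, adjusted p = 0.038, range 0.038 to 0.76).

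Mitosis genes fell in 47 of 47 cases, with the same counts adjusted over the list alone. Mitosis genes had a camera adjusted p of 3.7e-16 (adjusted p = 0.11 with an estimated correlation, range 1.3e-27 to 0.11), and CDCA3 fell by log2 1.20. S phase genes fell in 46 of 48 cases and were not called in 2, with the same counts adjusted over the list alone and a camera adjusted p of 3.1e-15 (adjusted p = 0.025 with an estimated correlation, range 5e-26 to 0.025), and EXO1 fell by log2 1.30. Cholesterol synthesis genes rose in 18 of 24 cases, fell in 1 and were not called in 5, with 19 higher and 1 lower adjusted over the list alone. Cholesterol genes had a camera adjusted p of 1.2e-05 (adjusted p = 0.13 with an estimated correlation, range 3.9e-08 to 0.13), and STARD4 rose by log2 1.00 ± 0.048. Keratinocyte genes rose in 13 of 23 cases, fell in 5 and were not called in 5, with the same counts adjusted over the list alone. Keratinocyte genes had a camera adjusted p of 0.012 (adjusted p = 0.46 with an estimated correlation, range 0.0047 to 0.46), and IVL, the involucrin gene, rose by log2 3.18 ± 0.17. Junction genes rose in 10 of 27 cases, fell in 5 and were not called in 12, with the same counts adjusted over the list alone and a camera adjusted p of 0.083. They were called without TGFb3 3 (adjusted p = 0.038) or control 3 (0.044), with no filter (0.029) and with a minimum of 5 TPM (0.042, range 0.029 to 0.59). CDH1 rose from 94.3 ± 7.03 to 182 ± 11.5 TPM. Cytosolic ribosomal protein genes were lower in 26 of 67 cases and not called in 41, with 0 higher and 23 lower adjusted over the list alone. Ribosomal protein genes had a camera adjusted p of 0.015 (adjusted p = 0.52 with an estimated correlation, range 0.00077 to 0.52), but 9 were lower and 3 higher after median ratio rescaling, where the list was not called (adjusted p = 0.17). Histones rose in 4 of 6 cases and were not called in 2, with the same counts adjusted over the list alone. Histones had a camera adjusted p of 0.021 (adjusted p = 0.12 with an estimated correlation, range 0.014 to 0.12), a call lost with no filter (0.06).

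The luminal, S100, interferon, apoptosis, p53, glycolysis and mitochondrially encoded lists were not called in TGFb3, with camera adjusted p between 0.12 and 0.88. Of the mitochondrially encoded genes 5 of 15 rose, 2 fell and 8 were not called, and MT-RNR2 rose from 5534 ± 419 to 9702 ± 211 TPM. LCN2 fell by log2 1.47, GADD45A, a p53 target, rose by 2.22 ± 0.051, hexokinase HK2 fell by 1.78 and GAPDH by 0.25 (adjusted p = 0.0056). The metallothionein MT1F rose by 0.91 ± 0.11, the endothelial marker KDR fell by 0.88, the leukocyte marker CSF1R rose by 2.41 ± 0.13 and CD14 fell by 2.57. For p53 targets the median was -0.02 (0.05 after median ratio rescaling) with a camera direction of up, for vacuolar ATPase subunits the mean was -0.10 with a median of 0.04, and for interferon genes 0.03 with a median of -0.10. Camera called 15 lists up and 5 down, and the calls of TGF-beta targets, mesenchymal genes and S phase genes held with an estimated correlation.

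High calcium against TGFb3 tested the difference between the treatments. FN1 was lower in high calcium than in TGFb3 by a log2 difference of -6.75 ± 0.063, and LCN2 (5.20 ± 0.084), the pyruvate dehydrogenase kinase PDK4 (5.10 ± 0.11) and GDF15 (4.92 ± 0.073) were higher. PDK4 was at 25.2 ± 0.765 TPM in the controls, 160.2 ± 2.79 TPM in high calcium and 3.76 ± 0.898 TPM in TGFb3. All 29 unfolded protein response genes and all 27 ATF4 targets were higher in high calcium, and 24 of 29 TGF-beta targets were lower.

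In this comparison 7038 genes were higher and 2256 lower of 13968, of which 1498 and 508 differed by a log2 of 1 or more (874 and 829 after quantile normalisation). The samples did not overlap in 71.2% of genes, where chance gives 10%, and the median log2 difference of all tested genes was 0.27. Of the calls 75.7% were higher. That share was 53.1% (4481 higher, 3954 lower) after median ratio rescaling, 59.5% (5100 and 3468) with mitochondrial genes left out, 51.1% (4364 and 4181) after quantile normalisation and 53.2% with both of the first steps.

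The unfolded protein response list had a camera adjusted p of 1.8e-11 (adjusted p = 0.07 with an estimated correlation, range 5.4e-18 to 0.07), with the same counts adjusted over the list alone and 28 higher and 0 lower after median ratio rescaling, and HSPA5 was higher by log2 2.87 ± 0.038. ATF4 targets had a camera adjusted p of 8e-09 (adjusted p = 0.077 with an estimated correlation, range 1.4e-14 to 0.077), with the same counts adjusted over the list alone and 27 higher and 0 lower after median ratio rescaling, and DDIT3 was higher by log2 3.76 ± 0.10. Of NRF2 targets 22 of 24 were higher and 2 not called, with the same counts adjusted over the list alone and 19 higher and 1 lower after median ratio rescaling. NRF2 targets had a camera adjusted p of 5.5e-06 (adjusted p = 0.062 with an estimated correlation, range 4.4e-10 to 0.062), with GCLC higher by log2 2.23 ± 0.051. TGF-beta and SMAD targets were lower in 24 of 29 cases, higher in 2 and not called in 3, with 2 higher and 25 lower adjusted over the list alone and 2 higher and 28 lower of 30 after median ratio rescaling. SMAD targets had a camera adjusted p of 7.5e-19 (adjusted p = 0.0059 with an estimated correlation, range 5.2e-23 to 0.0059), and TGFBI was lower by log2 -4.26 ± 0.050 and SMAD7 by -1.61 ± 0.094. Mesenchymal genes were lower in 23 of 34 cases, higher in 5 and not called in 6, with the same counts adjusted over the list alone and 3 higher and 28 lower after median ratio rescaling. Mesenchymal genes had a camera adjusted p of 1.8e-15 (adjusted p = 0.0059 with an estimated correlation, range 2.2e-16 to 0.0059), and COL4A1 was lower by -4.11 ± 0.052. S phase genes were lower in 36 of 48 cases, higher in 3 and not called in 9, with 4 higher and 37 lower adjusted over the list alone and 1 higher and 42 lower after median ratio rescaling and a camera adjusted p of 6.8e-16 (adjusted p = 0.022 with an estimated correlation, range 4.9e-19 to 0.022). Mitosis genes were lower in 37 of 47 cases, higher in 2 and not called in 8, with 4 higher and 38 lower adjusted over the list alone and 0 higher and 43 lower after median ratio rescaling. Mitosis genes had a camera adjusted p of 6.6e-16 (adjusted p = 0.12 with an estimated correlation, range 3e-19 to 0.12), and MYBL2 was lower by log2 -1.40 ± 0.061. Cholesterol synthesis genes were higher in 20 of 24 cases and not called in 4, with the same counts adjusted over the list alone and 17 higher and 2 lower after median ratio rescaling. Cholesterol genes had a camera adjusted p of 0.001 (adjusted p = 0.33 with an estimated correlation, range 1.4e-06 to 0.33).

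Of lysosomal hydrolases 34 of 52 were higher, 9 lower and 9 not called, with the same counts adjusted over the list alone and 27 higher and 11 lower after median ratio rescaling and a camera adjusted p of 0.25, called with no filter (0.014, range 0.014 to 0.33). CTSD was higher in high calcium by log2 1.04 ± 0.12 and CTSB lower by -1.59 ± 0.073. CTSL was higher by 0.39 ± 0.066 (adjusted p = 0.00049) but not called after median ratio rescaling (0.13, adjusted p = 0.14, range 0.00039 to 0.14). LAMP1 (log2 0.10 ± 0.043, adjusted p = 0.06) was called higher without TGFb3 1 (adjusted p = 0.037, range 0.014 to 0.19) and called lower after median ratio rescaling (-0.15, adjusted p = 0.014) and quantile normalisation (-0.11, adjusted p = 0.045). LAMP2 (-0.07 ± 0.041, adjusted p = 0.18) was called lower under the 3 other scalings, at -0.32, -0.26 and -0.26. TFEB had a log2 difference of 0.10 ± 0.095 (adjusted p = 0.36) and TFE3 of 0.01 ± 0.062 (adjusted p = 0.89), which was called lower under the 3 other scalings (-0.24, -0.24 and -0.18, adjusted p = 0.0071, 0.0054 and 0.037, range 0.0054 to 0.98). Autophagy genes were higher in 23 of 40 cases, lower in 5 and not called in 12, with the same counts adjusted over the list alone and 7 higher and 13 lower after median ratio rescaling and a camera adjusted p of 0.89. SQSTM1 was higher by log2 1.86 ± 0.065, WIPI1 by 1.24 ± 0.053, RCAN1 by 3.13 ± 0.049 and ATP2B1 by 1.53 ± 0.057.

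NF-kappaB targets were higher in 21 of 27 cases, lower in 2 and not called in 4, with the same counts adjusted over the list alone and 16 higher and 2 lower after median ratio rescaling. NF-kappaB targets had a camera adjusted p of 0.014 (adjusted p = 0.57 with an estimated correlation, range 0.0021 to 0.57), and SOD2 was higher by log2 3.92 ± 0.17. STAT3 was higher by 1.04 ± 0.052, CDH1 lower by -0.25 ± 0.060, TGFBR2 lower by -0.53 ± 0.035 and GAPDH higher by 0.41 ± 0.061. SOCS3 had a log2 difference of 0.14 ± 0.11 (adjusted p = 0.28), and LIF of 0.35 ± 0.16 (adjusted p = 0.078), called without TGFb3 2 (0.46, adjusted p = 0.043, range 0.043 to 0.82). The TGFB3 gene differed by log2 0.92 ± 0.25 (adjusted p = 0.0078), not called after quantile normalisation (0.59, adjusted p = 0.072, range 0.00032 to 0.072). Basal genes were lower in 10 of 19 cases, higher in 7 and not called in 2, with the same counts adjusted over the list alone and 6 higher and 11 lower after median ratio rescaling. The basal genes had a camera adjusted p of 0.001 (adjusted p = 0.077 with an estimated correlation, range 0.00085 to 0.077), and SNAI2 was lower by log2 -2.73 ± 0.072. Mitochondrially encoded genes were lower in 13 of 15 cases and higher in 2, MT-RNR1 and MT-RNR2, with the same counts adjusted over the list alone and 2 higher and 13 lower after median ratio rescaling and a camera adjusted p of 6.9e-13 (adjusted p = 0.062 with an estimated correlation, range 1.9e-13 to 0.062). Fibroblast markers were lower in 5 of 7 cases, higher in 1, S100A4, and not called in 1, with the same counts adjusted over the list alone and 1 higher and 6 lower after median ratio rescaling. Fibroblast markers had a camera adjusted p of 0.00056 (adjusted p = 0.062 with an estimated correlation, range 0.00033 to 0.062), and PDPN was lower by log2 -3.24 ± 0.081.

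Cytosolic ribosomal protein genes were higher in 51 of 67 cases and not called in 16, with the same counts adjusted over the list alone and 11 higher and 4 lower after median ratio rescaling. Ribosomal protein genes had a camera adjusted p of 0.0051 (adjusted p = 0.61 with an estimated correlation, range 1.3e-05 to 0.67), a call lost after median ratio rescaling (adjusted p = 0.67) and without mitochondrial genes (0.27). The S100 list, with 5 of 13 higher, 7 lower and 1 not called and the same counts adjusted over the list alone and 5 higher and 7 lower after median ratio rescaling, had a camera adjusted p of 0.022 (adjusted p = 0.57 with an estimated correlation, range 0.0093 to 0.57). Its call was lost under the 3 other scalings (adjusted p = 0.23, 0.32 and 0.15). Ligands, receptors and SMADs were higher in 7 of 17 cases, lower in 6 and not called in 4, with the same counts adjusted over the list alone and 5 higher and 8 lower after median ratio rescaling, and had a camera adjusted p of 0.049 (adjusted p = 0.57 with an estimated correlation, range 0.0064 to 0.57). That call was lost without control 1, 2 or 3 (adjusted p = 0.053, 0.051 and 0.07), high calcium 1, 2 or 3 (0.052, 0.051 and 0.059) or TGFb3 2 (0.056). It was also lost under the 3 other scalings (0.16, 0.14 and 0.13), with no filter (0.072) and with only the compared groups (0.069). In the lysosomal membrane, MiT/TFE, calcineurin, ligand and receptor, junction, heat shock and histone lists the median log2 difference was between 0.03 and 0.25, under the 0.27 of all genes, and the camera direction was down. After median ratio rescaling these medians lay between -0.18 and 0, and that of autophagy genes turned from 0.23 to -0.02. Means and medians differed in sign for immediate early genes (0.09 and -0.17) and for ligands and receptors (-0.05 and 0.11). Camera called 6 lists up and 9 down, and the calls of TGF-beta targets, mesenchymal genes and S phase genes held with an estimated correlation.

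The shared response of the treatments was compared across genes. Of 5812 genes called against the control in both, 2658 were higher in both, 1664 lower in both and 1490 opposite, where independent lists of these sizes would give 1707, 787 and 2761. The 100 simulated pairs of unchanged groups gave on average 0.02 genes higher in both, 0 lower in both and 0 opposite, so they set no expected overlap for lists of these sizes. After quantile normalisation 2599 were lower in both. JUN (log2 2.34 in high calcium and 2.73 in TGFb3), KLF4 (1.86 and 1.61) and TNC (4.13 and 4.30) rose in both, and EXO1 fell in both (-2.04 and -1.30). LCN2 (3.73 and -1.47) and GDF15 (3.53 and -1.40) went opposite ways. Of the genes higher in both, 982 were also higher and 612 lower in high calcium than in TGFb3. The covariance of log2 differences was 0.179, against 0.012 in simulated unchanged groups sharing controls. Pearson's r was 0.395 and Spearman's rho 0.457. Shared controls alone gave 0.498 (0.433 to 0.545 over 100 draws) and 0.459 in simulation, which is no reference for changed groups. The 3 controls cannot be split into parts of 2 samples each, so shared controls may add to the excess over independent lists.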

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

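Results were recomputed under the alternatives fixed before the data were examined. Genes under a mean of 5 TPM, and mitochondrial genes, have no value under the alternatives that leave them out, lists that fell under 5 tested members there have no test, and the shared response has no value with only the groups compared. Call counts were also recomputed under 1 alternative chosen after seeing the data (leaving out mitochondrial genes, then median ratio rescaling). Of 355 named gene results, all kept their direction and call with a pseudocount of 0.1 TPM, as did 339 with median ratio rescaling, 335 with quantile normalisation and 348 with no filter on low values. Leaving out 1 sample at a time left 5901 to 6430 genes higher and 2125 to 2398 lower in high calcium against control.

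Scalings moved the balance of calls most. High calcium against control had 3703 genes lower after median ratio rescaling, 3791 with mitochondrial genes left out and 3747 with both; quantile normalisation gave 3991 higher and 4464 lower, with 845 and 649 at a log2 of 1 or more. High calcium against TGFb3 had 4481 higher, 3954 lower and 985 higher by 1 or more with median ratios, 3468 lower without mitochondrial genes and 4553 higher, 4001 lower and 776 lower by 1 or more with both. Quantile normalisation gave 4364 and 4181 there, with 874 and 829 at 1 or more. By construction, these steps recentre each sample. With a minimum of 5 TPM, 911 and 975 genes were higher by 1 or more in high calcium against control and against TGFb3, because fewer genes were tested. With a pseudocount of 0.1 TPM 865 genes were lower by 1 or more in TGFb3, since a smaller pseudocount widens differences of low values.

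Directions reversed for genes near 0. By construction, median ratio and mitochondria-free scaling divide all genes of a sample by 1 factor, which lowered high calcium relative to the other groups (median ratio factors 1.092 to 1.106, control 0.952 to 0.988, TGFb3 0.919 to 0.931). For quantile normalisation the cause was not tested. Against control in high calcium, MT1E became -0.006 and GAPDH -0.023 with median ratios, and -0.022 and -0.039 without mitochondrial genes. FN1 became -0.168, -0.17 and -0.185 under median ratio, quantile and mitochondria-free scaling, and SMAD7 -0.148 with quantiles. Between the treatments TFE3 became -0.235, -0.236 and -0.181 under the same scalings, and LAMP1 -0.149 and -0.113 under the first pair.

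With an estimated correlation the hydrolase, membrane and autophagy lists in high calcium had adjusted p = 0.06, 0.32 and 0.069, and the hydrolase and membrane lists in TGFb3 0.11 and 0.23. Hydrolases in TGFb3 ranged from 0.028 to 0.078 over single samples left out, at 0.057 without control 3 and 0.078 without TGFb3 1, and had 0.065 with a minimum of 5 TPM. In high calcium, vacuolar ATPase subunits were called with no filter (0.0048) and with quantiles (0.041), and the MiT/TFE list with no filter (0.0087), median ratios (0.042) and no mitochondrial genes (0.043). For these lists the cause was not tested.

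The shared response had 2599 genes lower in both with quantile normalisation. Its covariance was 0.2918 with a pseudocount of 0.1 TPM, 0.1017 with no filter, 0.1697 with quantiles, 0.1954 without mitochondrial genes and 0.176 to 0.1911 over single samples left out. Its correlation was 0.377 with no filter, 0.4095 with a minimum of 5 TPM, 0.3811 with quantiles, 0.412 without mitochondrial genes and 0.3853 to 0.4106 over single samples left out. For these values too the cause was not tested.

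With the replicate number as a block, 6258 genes were higher and 2299 lower in high calcium, and 3589 and 4455 in TGFb3. Of the 355 gene results 352 had the same call with the block, and of the list results 97. As a pairing check, samples of the same number in different groups had residual correlations of -0.075 to -0.004, with 0 of 9 above 0.1, and those of different numbers -0.035 to 0.09. Sequencing depth is unknown, so its effect on low values could not be computed.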

Other observations

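The gene families named here were matched by symbol and chosen after the values were seen, and so were the tests on a like loss of all mitochondrial RNAs and on the distance from the promoter. In high calcium against control, 18 of 18 coat proteins of transport vesicles (COPI and COPII) were higher (camera adjusted p = 3.9e-07, 0.076 with an estimated correlation), with SEC24D at log2 2.86. Of 23 genes of the translocon, signal peptidase, signal recognition particle and its receptor 20 were higher and 1 lower (7.2e-04, 0.072 with an estimated correlation). After median ratio rescaling 16 coat protein genes and 17 of these 23 were higher. Of 12 tubulins 10 were lower and 2 higher (2.9e-07, 0.093 with an estimated correlation), TUBB4B at -1.83. Of 37 genes named after ribosome biogenesis or the nucleolus, NOL3 and NOL4L left out, 27 were lower and 3 higher in high calcium (5.4e-11, 0.072 with an estimated correlation). In TGFb3 34 of these were lower and 1 higher (2.3e-10, 0.044 with an estimated correlation), NOP56 at -1.33. There 13 of 15 collagens were higher (6.3e-07, 0.037 with an estimated correlation), and 72 of 78 mitochondrial ribosomal protein genes were lower (6e-14, 0.048 with an estimated correlation). After rescaling 69 of the latter were lower, with 0.058 with an estimated correlation, so that call is lost.

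The share of all mitochondrial RNA was 22.7% in the controls and 11.5% in high calcium, but a loss of mitochondria that lowers all their RNAs alike would not give higher ribosomal RNAs, and the mean of both ribosomal RNAs minus the median of the 13 messenger RNAs was log2 5.01 ± 0.35 (SE). Nuclear copies of mitochondrial genes did not take over the reads, gaining at most -3.19% of the TPM lost (7130 to 1780 TPM). With the ribosomal RNAs left out the median difference of the messenger RNAs was still -1.98 ± 0.34 (SE), so ribosomal RNA alone did not lower them. Weaker removal of RNAs without a poly(A) tail stays open. The 142 nuclear small RNA genes (median -0.07 ± 0.07, SE) cannot decide it, as short RNAs may be captured poorly. Of 6 replication-dependent histones 5 rose (median 0.84) while all 48 S phase genes fell. Distance from the heavy-strand promoter may matter (rho = -0.62 over 14 genes, one-sided permutation p = 0.011), but cannot be told apart from the contrast of ribosomal with messenger RNA, since over the 12 messenger RNAs rho was -0.4 (one-sided permutation p = 0.1). A response of mitochondria to calcium, ionomycin or both also stays open.

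If the high calcium treatment acts on mitochondria as a whole, nuclear genes for mitochondrial proteins could fall as well. Over 164 nuclear-encoded genes of the respiratory chain, its assembly, ATP synthase and the mitochondrial ribosome the difference relative to other genes was -0.3 ± 0.03 (SE), with 29 higher and 58 lower, between the bounds of -0.25 and -0.5 written before the test, so this stays undecided. After median ratio rescaling it was -0.31, with 9 higher and 95 lower. In TGFb3, where mitochondrial messenger RNA made up 21% of TPM against 21.6% in the controls, the difference was -0.39, with 1 higher and 129 lower, so lower values of these genes were not limited to high calcium.

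More genes higher than lower in high calcium may come in part from TPM freed by the lower mitochondrial messenger RNAs. With mitochondrial genes left out 55.1% of calls were higher, against 73% as deposited, and the median difference was 0.052. A larger share of nuclear or unspliced RNA in general was argued against, since 1080 noncoding nuclear genes differed from protein-coding genes of like expression by a median of -0.003 ± 0.027 (SE). Single nuclear RNAs went the other way, with MALAT1 at 158 TPM in the controls and 424 TPM in high calcium, and the share of long noncoding RNA was 1.049% and 1.583%. A real rise of many genes stays open, because TPM fixes the total.

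For lysosomal hydrolases higher in high calcium, freed TPM was not enough, since their median difference was 0.39 ± 0.1 (SE) with mitochondrial genes left out (adjusted p = 5.4e-04, 0.039 with an estimated correlation). Leukocytes, cells rich in lysosomes, were argued against by 5 of their marker genes, which summed to at most 1.6 TPM in high calcium, all of it FCER1G, and 0.805 TPM in the controls. PTPRC, TYROBP and AIF1 were listed at 0 in all 9 samples. All 14 leukocyte markers summed to 23.3 TPM in the controls and 66.1 TPM in high calcium, mostly CD14 (20 and 36 TPM) and CD68 (2.04 and 24.8 TPM), which are not limited to leukocytes. MCF10A is an established epithelial cell line, so leukocytes were unlikely from the start and this check could hardly have come out otherwise. The values show hydrolase RNA higher relative to other RNA in these cells, and the cause was not tested.

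Each comparison of 3 samples with 3 allows 10 splits, too few for a share under 0.05, and in each 1 of 10 splits, the real one, reached the real number of calls. High calcium against control gave 8816 called genes and at most 1 in another split. TGFb3 against control gave 8326 and at most 0, and high calcium against TGFb3 9294 and at most 1.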
